A study of Mus musculus with 6 samples.

How the data were processed

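RNA from tumors grown from 4T1 cells, a mouse mammary carcinoma line, was sequenced as paired-end libraries, per the labels. The cells were wild type or knocked out for Mki67, the gene of the proliferation antigen Ki-67, and were placed in the mammary fat pad of nude mice, which lack a thymus. Tumors were taken 3 weeks later, per the labels' protocols. The 6 libraries fall into 2 groups of 3, and the group and the replicate number of each were taken from its title.

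The deposited tables hold whole-number counts of read pairs per gene, not normalized, in an unstranded column and 2 stranded columns. STAR 2.6.0c, FastQC and DESeq2 with the GRCm38 build are named in the submitters' processing notes. The layout of the tables is that of STAR's gene counts, in which a read pair that maps to several places or overlaps exons of more than 1 gene is not counted for a gene. Genes with near-identical copies, or with exons that overlap another gene, are therefore counted in part. The first 4 rows of each table name no gene and stayed out of library sizes and tests. In the wild-type libraries, unmapped pairs made up 33.9%, 32.4% and 31.2% of all pairs, and in the knockout libraries 30.8%, 54.6% and 52.7%. Multimapping pairs made up 3.1% to 4.4% of all pairs. Of the uniquely mapped pairs, 9.2% to 11.1% lay outside annotated exons in the wild-type libraries and 14.2%, 9.9% and 18.9% in the knockout libraries, and 5.0% to 6.2% were ambiguous between genes over the 6 libraries.

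The first stranded column held 50.1% to 50.2% of the stranded counts in each library, so the unstranded column was used, under a rule fixed before the data were examined. Reads from a gene and from its antisense partner cannot be separated in such counts. Each table held 54146 gene rows, of which 54079 were matched by identifier to GENCODE M21, an annotation of the same build, for symbols and coordinates, and 67 were not matched. Where several identifiers shared a symbol, the symbol was kept for the one with the highest count.

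Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, estimateDisp, glmQLFit and glmQLFTest without robust estimation), with Benjamini-Hochberg adjustment over the 19900 genes tested and a threshold of 0.05 on the adjusted p. Standard errors (SE) are the absolute log2 fold change divided by the square root of the F statistic. CPM values were computed with TMM factors. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, two-sided, with adjustment over the 34 lists, all of which had at least 5 tested members. The lists hold 592 entries, 591 of which were found in the tables. They were also tested with an estimated correlation and with fry. fry tests whether the genes of a list move one way on balance, and does not compare the list with other genes.

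The tests, the lists and the rule for naming genes were fixed before the data were examined. The rule takes the 12 largest changes in each direction among genes past the threshold with a mean CPM of at least 2 and no overlap between the groups, up to 4 members with the smallest p in each list, 12 genes named in advance, and the 5 smallest p in each direction. Symbols without a proper name were skipped. It gave 169 genes. Krt8, Krt18, C1qa, Calr, Cxcl1, Pdgfra and Cd3e lie outside it and were chosen from the lists after their values were seen. Of the 169 genes, 18 had over 10% of their exonic bases covered by exons of other genes, among them Lemd1, Gzmf, Psmb8, Il1a, Erap1 and Xist.

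The alternatives were DESeq2 1.42.0 in place of edgeR, RLE size factors, library totals alone, no filter and a stricter filter on low counts, a stranded column, a robust fit, each of the 6 replicates left out in turn, the replicate number as a block, and the mitochondrially encoded genes with the 20 most abundant genes left out. The following were added after seeing the data: only libraries with under 40% unmapped pairs, the unmapped share as a covariate, the share outside exons as a covariate, and removal of each library's trend with GC content. The fitting steps were tested on simulated data made from the means and library sizes of this comparison, with 19425 genes in the step. Of the simulated 2-fold changes, 70 of 99 tested genes were recovered (70.7%), and of the 4-fold changes 85 of 96 (88.5%). Of the 161 calls, 6 were false (3.7%). The simulation changed 200 genes and gave both groups the same spread. The real comparison had far more calls and a wider spread between knockout libraries, so these rates need not carry over to it.

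Gene counts totalled 37065778, 38334962 and 38399826 read pairs in the wild-type libraries and 30772729, 25239215 and 22081970 in the knockout libraries. A count of 0 allows up to 3 counts, or 0.078 to 0.136 CPM depending on the library. Such limits and the counting intervals given cover counting error only, since no molecular identifiers are named in the labels. The labels do not say that the replicates came from separate mice, nor how many knockout clones were used, so p-values measure the spread between these samples. Counts of each pair of replicates within a group differed by more than sampling noise, with a chi-square per degree of freedom of 7.0 to 9.2 between wild-type libraries and 20.4 to 58.5 between knockout libraries.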

Results

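Transcript levels were compared between 3 libraries from wild-type and 3 from Mki67 knockout 4T1 tumors, 3 weeks after the cells were placed in the mammary fat pad of nude mice. The comparison asks how tumors from wild-type and from Mki67 knockout cells of the same line differ in gene expression. The number of knockout clones is not given in the labels. A difference between clones therefore cannot be told apart from an effect of the knockout in any result below. Gene counts per library ranged from 22081970 to 38399826 read pairs, and the 3 knockout libraries were the shallowest. The first principal component of log2 CPM carried 63.2% of the variance and separated the genotypes, and the second carried 21.3% and set knockout replicate 2 apart from the other knockout libraries. Correlations across genes were 0.992 to 0.993 within the wild-type group, 0.968 to 0.985 within the knockout group and 0.942 to 0.964 between them.

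Mki67 (ENSMUSG00000031004, GRCm38 chromosome 7, 135689784 to 135716361, minus strand) fell to about a 3.04-fold lower level in the knockout tumors. Its level was 360 CPM ± 34.9 (SD, n = 3) in wild-type and 118 CPM ± 19.9 (SD, n = 3) in knockout tumors, a log2 fold change of -1.61 (SE 0.14, edgeR adjusted p = 6.79e-05). Each knockout library lay below each wild-type library, in the direction of its label. The transcript was still counted in all 3 knockout libraries, at 98.7, 117 and 139 CPM.

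Of 19900 genes tested, 7158 passed the threshold, 3506 higher and 3652 lower in knockout tumors. At least 2-fold changes were found for 1886 higher and 1026 lower genes. This excess of higher genes lay mostly among lowly expressed genes. Between a mean log2 CPM of -1 and 0, 353 were at least 2-fold higher and 96 lower. Between 4 and 6 the numbers were 220 and 246, and above 6 they were 122 and 108. Of protein-coding genes, 2851 were higher and 3386 lower, and at 2-fold 1481 and 856. Of processed pseudogenes, 382 were higher and 25 lower, and at 2-fold 189 and 12. The values of the groups did not overlap for 50.5% of genes, where chance gives 10%. The count of all genes past the threshold fell to 4078, 4415 and 4479 without wild-type replicates 1, 2 and 3 in turn. The number of genes at least 2-fold higher was 3084 without knockout replicate 2, 1197 without wild-type replicate 1 and 1159 without wild-type replicate 3.

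The largest rises included Wnt7a, a secreted Wnt ligand, which went from 0.387 CPM ± 0.096 to 40.6 CPM ± 5.0 (SD, n = 3 each), a log2 fold change of 6.70 (SE 0.19, adjusted p = 3.86e-07). Tmprss6, a membrane serine protease, rose from 2.98 to 199.5 CPM (log2 fold change 6.06, SE 0.12). Tspan1, Ngfr, Faim2, B4galnt3, Myo3b, Plch2 and Lemd1 rose by 5.16 to 5.69 on the log2 scale. Lamb3, a chain of the epithelial basement membrane protein laminin-332, rose from 35.3 to 532 CPM (log2 fold change 3.91, SE 0.10, adjusted p = 2.22e-07), and Espn, an actin-bundling protein, rose by 3.09. Among the genes that fell, the transcription factor Pitx1 went from 45.5 CPM ± 0.98 to 0.565 CPM ± 0.14 (SD, n = 3 each; log2 fold change -6.34, SE 0.16, adjusted p = 2.22e-07). The proton channel gene Otop1 went from 49.9 to 0.773 CPM (log2 fold change -6.01, SE 0.14). Angpt1, a ligand of the endothelial receptor Tek, fell by 5.37 on the log2 scale, Pdgfc, a platelet-derived growth factor, by 4.44, and Amigo2 by 4.08. Olfr805, Gprin3 and Msx3 fell by 4.71, 4.60 and 4.50. Without knockout replicate 1, Olfr805 fell by 5.39 and Gprin3 by 5.44, and without knockout replicate 3, Msx3 fell by 5.09. For Fcrl6, 1049 counts in the wild-type group stood against 3 in the knockout group, a ratio of 249 after scaling by library size, with a 95% exact counting interval of 84.9 to 1210. For Grp, 780 counts stood against 4, a ratio of 139 after the same scaling (95% exact counting interval 54.0 to 511).

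Epithelial genes rose together. Of 24 measured members, 22 rose and none fell, also when adjusted over the list alone, and the median log2 fold change was 1.89 (camera adjusted p = 2.25e-15, adjusted p = 0.234 with an estimated correlation). The adhesion receptor gene Cdh1 rose 4.05-fold, from 105 CPM ± 16.7 to 427 CPM ± 24.2 (SD, n = 3 each; adjusted p = 1.42e-05), and Epcam 7.70-fold, from 117 CPM ± 15.7 to 902 CPM ± 37.1 (adjusted p = 1.76e-06). The keratin gene Krt7 rose 9.47-fold, Krt19 39.9-fold and the tight junction gene Cldn4 12.6-fold. Ap1m2 and Rab25, which act in epithelial membrane traffic, rose 48.6-fold and 45.2-fold. Of the list's 4 keratins, the most abundant ones moved least. Krt18 rose 1.33-fold, and Krt8 was at 1449 CPM ± 49.6 in wild-type and 1640 CPM ± 184 in knockout tumors (SD, n = 3 each), which did not pass the test (adjusted p = 0.223).

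Mesenchymal genes moved both ways, 12 higher and 4 lower of 20, and 14 and 4 when adjusted over the list alone (camera adjusted p = 0.0336 towards higher, adjusted p = 0.730 with an estimated correlation). The call of the list mesenchymal was lost without wild-type replicate 1 (adjusted p = 0.0780), wild-type replicate 2 (adjusted p = 0.06) or knockout replicate 2 (adjusted p = 0.167), with the unmapped share as a covariate (adjusted p = 0.213), with only libraries under 40% unmapped pairs (adjusted p = 0.372) and in fry (adjusted p = 0.190). Over all alternatives the adjusted p ranged from 0.00276 to 0.730, and without wild-type replicate 1 the number higher was 7. The list's median was largest in knockout replicate 2, at 0.86 against 0.29 and 0.45 in replicates 1 and 3. The genes that fell were Vim, an intermediate filament gene (2.25-fold lower, from 5241 CPM ± 138 to 2329 CPM ± 23.7, SD, n = 3 each), Fn1, fibronectin (1.74-fold lower), and the transcription factor genes Zeb2 (2.91-fold lower) and Twist1 (3.17-fold lower). Zeb1 was at 10.99 and 14.4 CPM and did not pass (adjusted p = 0.0701), while it did without knockout replicate 1, with a log2 fold change of 0.47 against 0.39 with all libraries. The matrix protease gene Mmp9 rose 22.8-fold, from 56.7 CPM ± 5.56 to 1290 CPM ± 379.

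**Figure D1:**
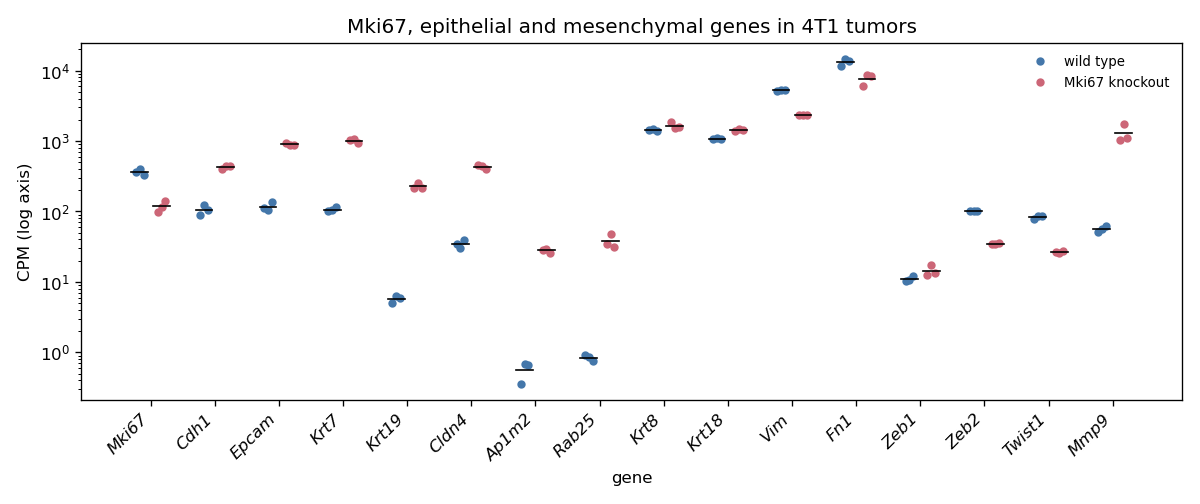
CPM on a log axis for Mki67 and for genes of the epithelial and mesenchymal lists, each point 1 library (3 wild type, 3 Mki67 knockout) and each bar the group mean. Krt7 rose 9.47-fold while Krt18 rose 1.33-fold, and Vim was 2.25-fold lower in the knockout tumors.

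Of the 34 lists, 18 passed the threshold and camera gave 0 with an estimated correlation, where the smallest adjusted p was 0.234 and 5 lists had an unadjusted p under 0.05; fry gave 17. Macrophage genes were lower in 17 of 18 measured cases, none higher, also adjusted over the list alone (median log2 fold change -1.55, camera adjusted p = 4.33e-11, adjusted p = 0.234 with an estimated correlation). Lyz2, lysozyme, went from 3494 CPM ± 392 to 317 CPM ± 16.1 (SD, n = 3 each; 11.02-fold lower, adjusted p = 7.27e-07). The scavenger receptor gene Msr1 was 7.82-fold lower and the complement gene C1qa 2.99-fold lower. Cx3cr1 and Trem2 fell by 2.35 and 1.81 on the log2 scale. Natural killer cell genes were lower for 9 of 10 tested members, also adjusted over the list alone (camera adjusted p = 1.05e-05, adjusted p = 0.234 with an estimated correlation). The granule protease gene Gzmb went from 11.5 CPM ± 2.29 to 0.322 CPM ± 0.22 (SD, n = 3 each), and Eomes fell by 3.55 on the log2 scale. Gzmb fell by 5.21 with all libraries and by 5.84 without knockout replicate 3. For Prf1, perforin, 2662 wild-type counts stood against 8 knockout counts, a ratio of 237 after scaling by library size (95% exact counting interval 120 to 549). Of the related granzyme genes, Gzmf fell by 8.82 and Gzmg fell by 8.15 on the log2 scale. Both lie on chromosome 14 and are similar in sequence, and pairs that map to both were not counted. Mast cell genes were lower for 6 of 10 members, none higher, also adjusted over the list alone (camera adjusted p = 0.00692, adjusted p = 0.550 with an estimated correlation). The number lower was 1 without wild-type replicate 2 and 2 without wild-type replicate 3 or knockout replicate 3, and the call was lost in fry (adjusted p = 0.0657) and with the stricter filter (adjusted p = 0.0573), over a range for the list mast cell of 3.66e-05 to 0.550.

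Genes of antigen presentation on MHC class I were lower for 15 of 18 members and higher for 1, Calr, also adjusted over the list alone (camera adjusted p = 2.03e-05, adjusted p = 0.536 with an estimated correlation). B2m went from 1380 CPM ± 134 to 974 CPM ± 47.1 (SD, n = 3 each; adjusted p = 0.00659), and the immunoproteasome gene Psmb8 was 3.22-fold lower. H2-K1 fell by 0.57 on the log2 scale, a call that was lost with the unmapped share or the share outside exons as a covariate. H2-Q6 and H2-Q7, near-identical copies, fell by 1.16 and 1.41. Interferon response genes were lower for 13 of 26 and higher for 2, and for 14 and 2 adjusted over the list alone (camera adjusted p = 0.000702, adjusted p = 0.550 with an estimated correlation), with Gbp2 falling by 1.39, Ifit2 by 1.38 and Ifih1 by 1.25. With the share outside exons as a covariate, 9 MHC class I genes and 7 interferon response genes were lower. MHC class II genes rose for 4 of 8, and for 6 adjusted over the list alone (camera adjusted p = 0.0404, adjusted p = 0.536 with an estimated correlation), and H2-Ab1 rose by 0.91. The call of the list MHC class II was lost without wild-type replicate 1 (adjusted p = 0.0868), knockout replicate 1 (adjusted p = 0.0806) or knockout replicate 2 (adjusted p = 0.167), without the filter on low counts (adjusted p = 0.0786), with the unmapped share as a covariate (adjusted p = 0.0677) and with only libraries under 40% unmapped pairs (adjusted p = 0.171). Over all alternatives the adjusted p ranged from 0.0202 to 0.536, and without wild-type replicate 1 the number higher was 2.

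Cytokine genes moved in opposite directions, 12 higher and 4 lower of 19, also adjusted over the list alone, and the list did not pass camera (adjusted p = 0.0835). It passed without wild-type replicate 2 (adjusted p = 0.0357) and with the stranded column (adjusted p = 0.0415), its adjusted p in camera ranged up to 0.550 over the alternatives run, and without wild-type replicate 1 the number higher was 7. Il1a, interleukin-1 alpha, went from 5.06 CPM ± 1.03 to 85.8 CPM ± 1.24 (SD, n = 3 each; 16.9-fold higher, adjusted p = 8.08e-07), and Cxcl1, a neutrophil attractant, rose 4.32-fold. Ccl2, a monocyte attractant, went from 70.9 CPM ± 10.9 to 6.94 CPM ± 0.96 (10.2-fold lower, adjusted p = 3.36e-06). Ccl7, of the same family, fell by 2.06 on the log2 scale, and Csf1, a macrophage growth factor, was 3.20-fold lower. Neutrophil genes rose for 10 of 19 and fell for 2, and for 13 and 2 adjusted over the list alone (camera adjusted p = 0.00088, adjusted p = 0.272 with an estimated correlation), with Csf3r rising by 1.14, and 0 fell without wild-type replicate 1, wild-type replicate 2 or knockout replicate 3, while 1 fell without wild-type replicate 3.

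**Figure D2:**
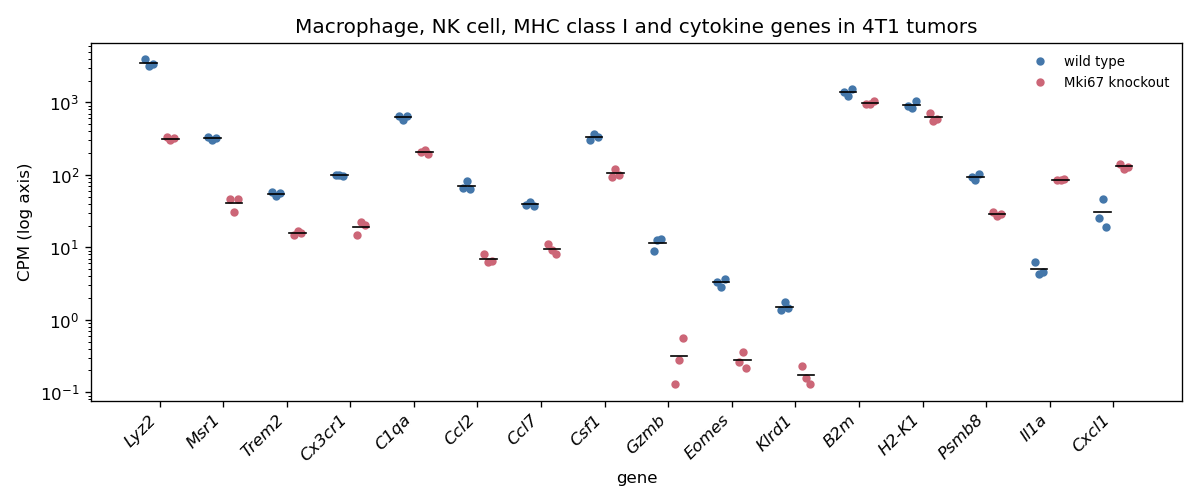
CPM on a log axis for genes of the macrophage, natural killer cell, MHC class I and cytokine lists, each point 1 library (3 wild type, 3 Mki67 knockout) and each bar the group mean. Lyz2 was 11.02-fold lower and Ccl2 10.2-fold lower in the knockout tumors, and Il1a was 16.9-fold higher.

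Genes of several lists named for other tissue components rose, though the counts do not show which cells expressed them. Fibroblast and matrix genes rose for 22 of 24, with Pdgfra falling, also adjusted over the list alone (camera adjusted p = 1.60e-06, adjusted p = 0.550 with an estimated correlation), and Fbln2 went from 516 CPM ± 46.1 to 1345 CPM ± 100 (SD, n = 3 each). The fibroblast list's median rise was largest in knockout replicate 2, at 1.38 against 0.80 and 0.82 in replicates 1 and 3, and was 0.77 without that library. Pericyte and smooth muscle genes rose for 11 of 15, also adjusted over the list alone (camera adjusted p = 2.42e-05, adjusted p = 0.536 with an estimated correlation), among them Notch3 with a 6.04-fold rise. Adipocyte genes rose for 13 of 13, also adjusted over the list alone (camera adjusted p = 9.77e-06, adjusted p = 0.550 with an estimated correlation). Adipoq was at 13.7, 47.0 and 20.5 CPM in the knockout libraries, with replicate 2 the highest, and at 3.63 CPM ± 1.0 (SD, n = 3) in wild-type tumors, and its log2 fold change was 2.90 with all libraries and 2.18 without knockout replicate 2. Keratinocyte genes rose for 13 of 15, and for 14 adjusted over the list alone (camera adjusted p = 0.000248, adjusted p = 0.550 with an estimated correlation). Krt14 went from 41.9 CPM ± 10.7 to 818 CPM ± 189.5 (SD, n = 3 each), and the list's median rise was largest in knockout replicate 2, at 3.29 against 1.64 and 1.18 in replicates 1 and 3. Not all members followed that order. In knockout replicates 1, 2 and 3, Krt77 was at 9.01, 21.65 and 4.69 CPM and Dsg1a at 9.53, 25.2 and 6.20 CPM. Krt15 was at 8.91, 8.14 and 9.25 CPM. The number of keratinocyte genes higher was 5 without wild-type replicate 1 and 6 without wild-type replicate 3. Skeletal muscle genes rose for 11 of 14, also adjusted over the list alone (camera adjusted p = 0.000106, adjusted p = 0.453 with an estimated correlation), while 6 were higher without wild-type replicate 1 or 3 and 7 without knockout replicate 3.

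Genes of mitosis rose slightly, 7 of 20 with none lower, also adjusted over the list alone (camera adjusted p = 0.0182, adjusted p = 0.686 with an estimated correlation), with Birc5 rising by 0.59 and Tpx2 by 0.51 on the log2 scale. The call of the list mitosis was lost without wild-type replicate 2 (adjusted p = 0.0860), wild-type replicate 3 (adjusted p = 0.113), knockout replicate 2 (adjusted p = 0.167) or the filter on low counts (adjusted p = 0.204), with the unmapped share as a covariate (adjusted p = 0.0628) and with only libraries under 40% unmapped pairs (adjusted p = 0.372). Over all alternatives the adjusted p ranged from 0.00304 to 0.686, and the number higher was 4 without wild-type replicate 2 and 3 without wild-type replicate 3. Genes of cholesterol synthesis rose for 11 of 18, and for 13 adjusted over the list alone (camera adjusted p = 0.000585, adjusted p = 0.536 with an estimated correlation), among them Fdft1, which rose by 0.86. The number of these genes higher was 5 without wild-type replicate 1, wild-type replicate 3 or knockout replicate 3, and 6 without wild-type replicate 2. Immediate early genes rose for 10 of 14, and for 13 adjusted over the list alone (camera adjusted p = 0.0002, adjusted p = 0.453 with an estimated correlation), with Junb rising by 1.03 and Fos by 0.94, and 6 were higher without wild-type replicate 1 or 2. Stem cell associated genes rose for 8 of 14 and fell for 1, and for 10 and 1 adjusted over the list alone (camera adjusted p = 0.0072, adjusted p = 0.272 with an estimated correlation), with Sox9 rising by 0.86 and Myc by 0.67. The call of the list stem cell associated was lost without knockout replicate 2 (adjusted p = 0.0583) and with only libraries under 40% unmapped pairs (adjusted p = 0.0648). Over all alternatives the adjusted p ranged from 0.000982 to 0.272, and without wild-type replicate 1 or 2 the number higher was 5.

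**Figure D3:**
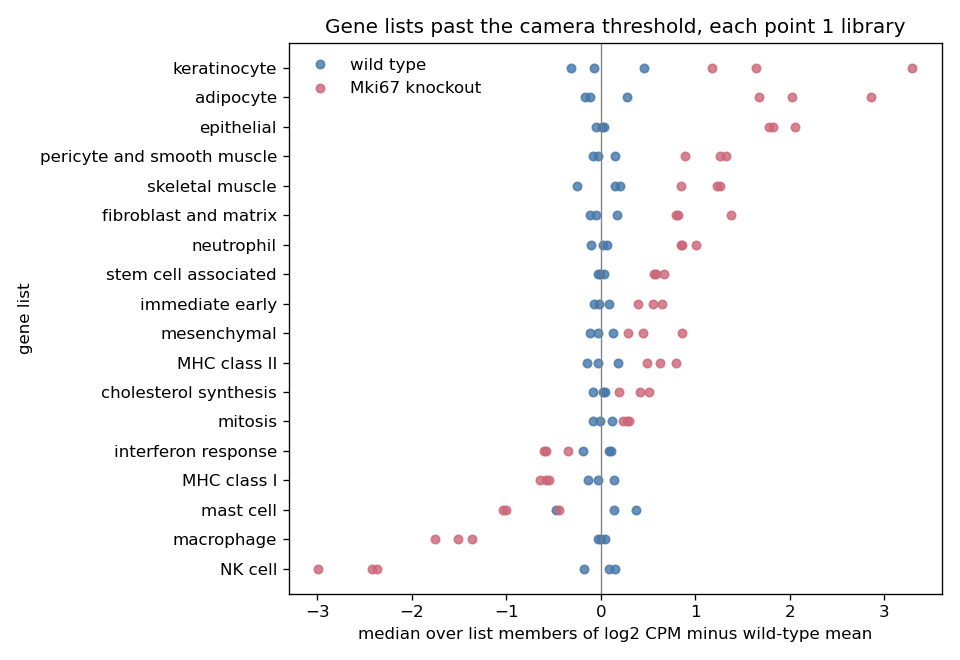
The 18 gene lists past the camera threshold, each point 1 library, on the median over members of log2 CPM minus the wild-type mean. The epithelial list stood at 1.77 to 2.06 and the macrophage list at -1.76 to -1.36 in the 3 knockout libraries.

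The remaining lists did not pass camera with all libraries. DNA replication genes were 5 higher and 2 lower of 24, with Mcm5 rising by 0.62 and Tyms falling by 0.59. Mcm5 lies on chromosome 8, whose genes were higher as a group (see the last section). Chromatin repression genes were 3 higher and 4 lower of 20, with Ezh2 rising by 0.60 and Rnf2 falling by 0.79. These counts were equal when adjusted over the list alone. With 1 library left out, 2 to 5 replication genes were higher and 1 to 5 lower, and 9 and 7 repression genes were lower without knockout replicates 1 and 2. The repression list passed without the filter on low counts (adjusted p = 0.0333), over a camera range of 0.0333 to 0.777. Genes regulated by p53 were 7 higher and 4 lower of 20 (7 and 5 adjusted over the list alone), with the cell cycle inhibitor gene Cdkn1a rising by 0.77. Hypoxia and glycolysis genes were 7 higher and 4 lower of 20 (8 and 4 adjusted over the list alone), with Vegfa rising by 1.28 and Adm falling by 2.21. Xenobiotic metabolism genes were 7 higher and 6 lower of 28 (8 and 7 adjusted over the list alone), with the transporter genes Abcc3 and Abcb1b falling by 1.21 and 0.69, and 3 were higher without wild-type replicate 1 or 2 and 4 without wild-type replicate 3. Aldh1a1, an aldehyde dehydrogenase gene, was at 0.925 CPM ± 0.40 and 1.99 CPM ± 0.46 (SD, n = 3 each; adjusted p = 0.0412). Its call was lost without wild-type replicate 1 or 2 (adjusted p = 0.141 for both) and without knockout replicate 1 (adjusted p = 0.0829) or 3 (adjusted p = 0.111), over a range of 0.00643 to 0.178 for all alternatives. Notch pathway genes were 9 higher and 2 lower of 19 (9 and 3 adjusted over the list alone), with Jag1 rising by 1.33. The Notch list passed without wild-type replicate 3 (adjusted p = 0.0253), knockout replicate 1 (adjusted p = 0.0418) or knockout replicate 3 (adjusted p = 0.0345) and with the share outside exons as a covariate (adjusted p = 0.00828), over a camera range up to 0.779, and 5 were higher without wild-type replicate 1 or 2. Wnt pathway genes were 9 higher and 4 lower of 19, with Fzd7 falling by 1.07, and unfolded protein and amino acid stress genes were 3 higher and 4 lower of 16, with the same counts adjusted over the list alone. Without wild-type replicate 1, 5 Wnt pathway genes were higher, and with 1 library left out 0 to 4 stress genes were higher and 0 to 4 lower.

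Endothelial genes were 2 higher and 1 lower of 20 (1 and 1 adjusted over the list alone), with Flt1 falling by 0.61. T cell genes were 2 higher and 1 lower of 8, also adjusted over the list alone, B cell genes 3 higher and 2 lower of 7 (4 and 2 adjusted over the list alone), and dendritic cell genes 4 higher and 1 lower of 12 (4 and 2 adjusted over the list alone). In edgeR with 1 library left out, the number higher ranged from 0 to 4 for endothelial, from 0 to 4 for B cell and from 1 to 5 for dendritic cell genes. Mammary gland genes were 2 higher of 9 (1 adjusted over the list alone). The signs of median, mean and test differed for 3 lists, with medians of -0.07 for DNA replication, -0.02 for endothelial and -0.05 for mammary gland genes, means of 0.03, 0.07 and -0.22, and a camera direction towards higher for each. With 1 library left out, the medians ranged from -0.175 to -0.012 for DNA replication, from -0.179 to 0.101 for endothelial and from -0.447 to 1.302 for mammary gland genes. The highest endothelial and mammary gland values came without wild-type replicate 3 and the lowest without knockout replicate 2, and with library totals alone these medians were 0.042 and 0.006. The number of mammary gland genes higher was 1 when a wild-type library or knockout replicate 2 was left out. Of 7 erythroid genes, 0 passed the edgeR test, also adjusted over the list alone, and 1 had an unadjusted p under 0.05. The erythroid list passed camera without wild-type replicate 3 (adjusted p = 0.0248), without the filter (adjusted p = 0.0234) and with the replicate block (adjusted p = 0.0350), over a camera range up to 0.550. Hbb-bs ranged from 81.9 to 263.7 CPM in wild-type and from 184 to 479.8 CPM in knockout tumors, and it passed without knockout replicate 2 (log2 fold change 1.11). Mitochondrially encoded genes were 3 higher of 13 (1 adjusted over the list alone), with 10 higher without knockout replicate 1 and 1 when any of the other libraries was left out alone. This list passed camera without knockout replicate 1 (adjusted p = 0.000615), with the stranded column (adjusted p = 0.0408), with the replicate block (adjusted p = 0.0386) and with the GC trend removed (adjusted p = 0.0418), over a camera range up to 0.917, and mt-Co2 was at 111 CPM in knockout replicate 1 and at 237 and 259.5 CPM in replicates 2 and 3. The call of mt-Co2, with a log2 fold change of 0.87, was lost without any 1 library except knockout replicate 1, with changes of 0.65 to 0.88. Xist, the RNA of the inactive X chromosome, was at 83.4 CPM ± 8.58 and 53.1 CPM ± 21.3 (SD, n = 3 each) and did not pass (adjusted p = 0.0642), while it fell by 1.07 on the log2 scale without knockout replicate 2.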

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

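The test on olfactory receptor genes was set out before its result was seen. The other tests of explanations here were chosen after the result was seen, as were the fits with covariates.

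Some of the counts that belong to no gene stood above the level of the wild-type libraries. The unmapped share was 54.6% in knockout replicate 2 and 52.7% in knockout replicate 3, against 30.8% in knockout replicate 1 and 31.2% to 33.9% in wild-type libraries. The share of uniquely mapped pairs outside exons was 14.2% in knockout replicate 1 and 18.9% in knockout replicate 3, against 9.9% in knockout replicate 2 and 9.2% to 11.1% in wild-type libraries. The multimapping share was 4.4% in knockout replicate 1, against 3.1% and 3.4% in knockout replicates 2 and 3 and 4.0% in the wild-type libraries.

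Lowly expressed genes were more often higher than lower. Among 1847 genes with a mean log2 CPM of at most -1, 165 rose and 55 fell, while among 5164 genes between 4 and 6, 813 rose and 1451 fell. General derepression of silent genes stays open. The lowest genes' median difference from wild type was 0.52, -0.06 and 0.77 in knockout replicates 1, 2 and 3. Between log2 CPM -1 and 0 it was 0.407, 0.077 and 0.71, again smallest in replicate 2. For the more expressed genes between log2 CPM 0 and 1 it was 0.195, 0.365 and 0.436. Reads from unspliced RNA or genomic DNA stay a candidate source too. The summed CPM of 1383 olfactory receptor genes at or under 1 CPM in every library was at least 1.92 times the highest wild-type value in knockout replicates 1 and 3, the libraries with the high shares outside exons, and 0.46 times it in replicate 2.

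The epithelial list rose with a median of 1.89, and the keratinocyte list with one of 2.43. A larger share of epithelial tumor cells alone would raise alike the members that only those cells express. Here 17 of 24 members lay over 2 SE from the median, and the changes of Krt8 and Krt18 were 0.18 and 0.41. Members that other cells express too need not rise alike, so this cannot decide, and a larger share beside other causes stays open. Gained segments spanning many genes were argued against as the whole cause: the median was 1.79 after subtracting that of each gene's 20 nearest genes outside the list, which stood at -0.468 to 0.507. In knockout replicates 1, 2 and 3 the epithelial median was 1.82, 2.06 and 1.77, and the keratinocyte median 1.64, 3.29 and 1.18. The epithelial rise thus varied less between these libraries than the keratinocyte rise, though in the same order. Skin epithelium in several knockout pieces, a state of the tumor cells that goes with the knockout, and a difference between cell clones unrelated to Mki67 stay open and were not tested.

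Macrophage genes fell beside higher fibroblast, adipocyte and keratinocyte genes. A smaller share of tumor cells would raise the markers of every host cell type. It therefore cannot alone give the macrophage median of -1.55 with 17 of 18 members lower. That median is part of the pattern itself, so a smaller share beside a separate fall of macrophage genes stays open. Fat or skin in knockout replicate 2 alone was argued against as the whole source, since without that library the adipocyte median was 1.79 and the keratinocyte median 1.28, both past camera's threshold. Fewer macrophages of unchanged kind cannot be told apart from a change in their expression, since 8 of 18 members lay over 2 SE from the median. Fat, skin or muscle at the edge of several knockout pieces stays open.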

How the results depend on the processing

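Each count of genes past the threshold stayed within 1.5 times its reported value under the planned changes of test, scaling, filter, column and fit. Leaving out 1 replicate at a time gave 4078 to 9301 genes past the threshold, 1821 to 4648 higher, 2257 to 4778 lower and 1159 to 3084 genes at least 2-fold higher; the low ends came without a wild-type library. With the unmapped share as a covariate, an alternative chosen after seeing the data, 2327 genes were higher and 984 at least 2-fold higher. With the share outside exons, chosen likewise, 2232 were lower. The unmapped share was high in knockout replicates 2 and 3 only, at 54.6% and 52.7%. That covariate thus largely sets these libraries apart, and the genotype difference rests mostly on knockout replicate 1. Calls lost in this fit therefore need not come from mapping quality. The cause of the changed counts was not tested. Only libraries under 40% unmapped pairs, also chosen after seeing the data, left knockout replicate 1 against 3 wild-type libraries, with the lone library assumed to vary like them, and gave 7903 genes. The Mki67 level stayed lower in every alternative run, with a log2 fold change of -1.93 to -1.50. With an estimated correlation camera called 0 lists. fry called 17, among them 16 of the 18 and the cytokine list, and lost the mesenchymal list (adjusted p = 0.190) and the mast cell list (adjusted p = 0.0657). Within called lists, the fit with the unmapped covariate gave 7 pericyte genes higher (11 without the covariate), 7 cholesterol (11), 5 skeletal muscle (11), 5 keratinocyte (13) and 2 MHC class II genes (4), and 2 mast cell genes lower (6). The fit with the share outside exons gave 6 cholesterol (11) and 6 skeletal muscle genes (11) higher, and 2 mast cell (6), 9 MHC class I (15) and 7 interferon response genes (13) lower. DESeq2 and the robust fit do not enter camera and gave no value for lists. The replicate block gave 6662 genes; same-numbered libraries had correlations of deviations of 0.05, -0.21 and -0.24, so the numbers were not taken to pair the samples, and not every library correlated best with its own number.

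Of the named genes, calls were lost for 20 with the unmapped share as a covariate, for 15 with the share outside exons, for 15 with only libraries under 40% unmapped pairs, and for 1 to 18 with 1 replicate left out. A sign changed for 5 values. Leaving out 1 replicate at a time, the gene Csn1s1 ranged from -3.43 to 0.43 and the gene Csn1s2a from -3.74 to 1.302 on the log2 scale, positive only without wild-type replicate 3; neither passed the threshold with all libraries. With only libraries under 40% unmapped pairs, mt-Co2 was at -0.063 and mt-Atp6 at -0.25, and with the unmapped share as a covariate mt-Atp6 was at -0.068. Depth limits the low genes, since 22081970 gene counts in the shallowest library leave up to 0.136 CPM for a count of 0.

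The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. In edgeR the real split gave 7158 genes and 2912 with at least 2-fold changes, and the highest of the others gave 0 in both (at an unadjusted p under 0.05, 9273 against at most 894). The real split was the 1 split with as many genes in both counts. For lists, 2 splits gave as many: the real one with 18, and wild-type replicates 1 and 2 with knockout replicate 1 against the rest, also with 18. Each of the remaining splits called lists too, from 5 to 15. With the preset correlation, camera thus called lists for mixed groupings of the libraries as well. Every other split held both genotypes in each group. Part of the genotype difference thus stayed between its groups, so these list calls need not be false. The rest widened the spread within the groups, which lowers the number of genes past the threshold. The 0 genes are therefore no measure of what unrelated groups would give.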

Other observations

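The genes in the following paragraphs were chosen after their values were seen, as were the tests on chromosome 8 and on imprinted genes.

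Among genes of laminin chains and integrins, values moved both ways. Lama3 went from 17.2 to 339.9 CPM (log2 fold change 4.30, SE 0.13, edgeR adjusted p = 4.32e-07). The integrin gene Itgb6 rose by 5.00 and Itgb4 by 1.03 on the log2 scale, while Itga6 fell by 0.37. Of 11 genes grouped under the symbol stem Itgb, 2 were higher and 4 lower, and of 12 under Itga, 4 were higher and 4 lower. The laminin chains Lamb1 and Lamc1, of other basement membranes, fell by 0.50 and 0.46. Among 386 groups of genes that share a symbol stem, 24 passed camera with the preset correlation, the first being the guanylate-binding proteins (9 of 11 lower, adjusted p = 0.000689) and the keratins (21 of 39 higher, adjusted p = 0.00337). With an estimated correlation the adjusted p was 0.991 for both.

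Of T cell receptor constant genes, some were higher in these tumors of nude mice. Trac went from 0.295 to 3.53 CPM (log2 fold change 3.56, and 4.61 without wild-type replicate 3), Trbc1 from 1.62 to 11.4 CPM and Trdc from 0.296 to 1.79 CPM, while Trbc2 was at 0.764 and 1.73 CPM and did not pass (edgeR adjusted p = 0.113). Cd3e, a chain of the same receptor complex, was at 0.572 and 0.912 CPM (edgeR adjusted p = 0.414), and Lck, a kinase of T cells, fell by 1.01 on the log2 scale. The T cell list did not pass camera (adjusted p = 0.763).

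Protein-coding genes of chromosome 8 were higher as a group. Over 569 genes with a mean log2 CPM above 3, the median change stood 0.498 above that of all such genes, and 0.492, 0.476 and 0.489 above it in knockout replicates 1, 2 and 3. Chromosomes 14 and 6 stood 0.291 and 0.234 above it, while chromosomes 3, 7, 12 and 5 differed from it by -0.185, -0.17, -0.134 and -0.123. A gained copy of chromosome 8, or of a large part of it, in the knockout cells may account for this. The test does not decide: 100% of its 12 windows of 10 Mb lay above the median of all genes, by 0.404 to 0.671, but the chromosome was chosen for its high median. All 9 windows of chromosome 14 and all 9 of chromosome 18, which stands 0.096 above, did so too, while 0% of the windows of chromosomes 5 and 7 did. Among the genes named above, Mcm5, Junb and Cdh1 lie on chromosome 8 and rose by 0.62, 1.03 and 2.02. Msr1 lies there too and fell by 2.97. The rise of Mcm5 is near the shift of the chromosome and may be part of it. DNA was not analysed here.

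H19 and Airn, RNAs of imprinted loci, fell by 4.29 and 4.03 on the log2 scale. A hypothesis that imprinted genes change more than others was tested on a list written after these values were seen, first with both genes in it and then without them. Of 35 listed genes, 27 were tested, H19 and Airn among them. Without them, 14 of 25 genes were higher and 3 lower, and the median absolute log2 change of 1.02 lay at percentile 100 of 10000 lists matched on expression, whose median was 0.42. Imprinted genes such as Dlk1, Meg3, Rian and Mirg on chromosome 12 lie close together and may move together. The matched lists do not copy this, so the percentile may be too high. Several of the list's genes, such as Dlk1 and Meg3, are also expressed in stromal cells, and the fibroblast list rose too, so the result may not be about imprinting.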
